A study of Escherichia coli with 20 samples.

How the data were processed

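The samples were 20 PAR-CLIP libraries from Escherichia coli MG1655 rph+, 10 from a strain whose Hfq protein carries a FLAG tag (Hfq-FLAG) and 10 from the wild-type (WT) strain. Cells grew at 37 °C in rich defined medium with 4-thiouridine to mid log phase. They were irradiated with long-wavelength UV light and lysed by sonication, and extracts of both strains went through the same anti-FLAG purification. Per the labels, the purified proteins were run on a gel and transferred to nitrocellulose, RNA was released with proteinase K, and libraries were made with the NEBNext Small RNA kit. The titles add a letter (A to E) and a replicate number (1 or 2) whose meaning the labels do not state, so both were treated as unknown structure, and libraries were compared unpaired, with blocks for either among the alternatives.

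The submitters' processing notes name cutadapt for adapter removal and Bowtie2 for alignment, with versions and settings not given in the sources used here. The deposited tables hold counts, namely the number of A, C, G and T read bases covering each position of the MG1655 chromosome, with no normalization. In each table the 4 base counts added up to the coverage column. The tables carry no strand, and 9 of the 20 held a continuation block to the right of the first 1048575 lines, which was read as part of the same library. In 1 of these the block was shifted by a column and was realigned. The authors' allele calls and bias columns were not used.

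Because the tables hold depth and not reads, the depth over a gene or window was summed and divided by 26, the median summed depth of isolated covered runs whose highest depth was 2, and then rounded. The quotients are called counts below. The planned estimate from runs at depth 1 was replaced by depth 2 because 89.1 to 93.9% of listed positions had an even depth. For the same reason read bases may not be independent, and the number of separate fragments behind them may be lower. Gene positions and locus tags came from the RefSeq table of the MG1655 assembly, which lists 4651 genes without strand. No genome sequence was used here, and a consensus was built from the pooled base counts at positions with a depth of at least 50 and a leading base share of at least 0.7. The strand was read from start and stop codons for 4094 of 4290 coding sequences and from a terminal run of at least 4 T for 71 of 107 ncRNA genes. Reads could not be assigned to a strand, so overlapping genes share their counts.

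Gene counts were compared with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood test, no block) under R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold, and 50-nt windows were tested in the same way. Shares of RNA classes and substitution percentages per library were compared by two-sided permutation tests with 100000 resamples, or exact permutation tests where n was 5. The location and sequence of called windows were compared by Fisher's exact test. Substitutions per gene and per window were tested with limma 3.58.1 on the log odds (pseudocount 0.5), with libraries of the same genotype and letter summed, 5 letters against 5, at a minimum of 100 read bases per letter for genes and 30 for windows. T-to-C changes were counted at transcript T, which reads as A-to-G on the + strand for genes of the other strand. The 13 gene lists (506 symbols, 501 matched) were tested with camera at a preset correlation of 0.01, with fry and with an estimated correlation beside it. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 did the remaining computation, and DESeq2 1.42.0 and limma-voom served as alternatives.

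The tests, thresholds, lists and naming rule were chosen before the data were examined, except for the per-gene, per-window and per-class substitution tests. Genes were named when they passed the 20-library fit and also an adjusted p of 0.05 with the same sign after summing within letters (5 against 5) and within title replicate numbers (2 against 2). From these the rule took the 15 largest rises and 5 largest falls at or above the median abundance, and up to 4 called members per list. It always named hfq and the list of stable ncRNAs of other protein complexes. For windows, the rule asked for the 5 largest rises at or above the median abundance that overlap no annotated gene, and none of the windows called in the 20-library fit qualified, since each overlapped a gene. The remaining called genes, the listed sRNAs outside the rule, the peaks and all substitution sites were chosen after their values were seen.

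Summed depth per library ran from 10249480 to 52855004, counts in genes from 386100 to 1981106, and counts outside rRNA genes from 33351 to 416753. The libraries were amplified without molecular identifiers, so any interval covers counting error and the spread between libraries, not copies of the same molecule. P-values measure only the spread between these libraries. On simulated data built from the deposited counts with 200 changed genes, the 20-library test recovered 85.1% of 2-fold and 100% of 4-fold changes, and 4.94% of its calls were unchanged genes. Recovery of 2-fold changes was 79% at 5 against 5, 63% at 2 against 2 and 84.0% for windows. The substitution test was tried on data with set depths, base shares and letter spread, not built from the deposited counts, and recovered 99.5% of 6-fold changes. On simulated counts the list test recovered the 1 raised list and called no other. All simulated libraries were drawn independently, although WT libraries of the same letter resembled each other. These rates may therefore not carry over to the real libraries.

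Alternatives covered the scaling (DESeq2 size factors, total counts only, factors from rRNA and tRNA genes), the tool, the filter on low counts, leaving rRNA genes out, the highest depth per gene, blocks for title replicate number and letter, sums over letters or replicate numbers, each title replicate alone, and leaving out each library in turn. Shifted windows, a 4-fold threshold, a run of 6 T and a depth of at least 20 were tried as well. Chosen after seeing the data were fits without the WT libraries of letters A and B, 5 letters against 3, 60 units of depth per count, list tests at 5 against 5, and the substitution alternatives.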

Results

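Hfq is an RNA chaperone that helps small regulatory RNAs (sRNAs) pair with messenger RNAs. PAR-CLIP marks RNA that touches a protein, because 4-thiouridine cross-linked by UV light is read as C instead of T after sequencing. RNA from anti-FLAG purifications of the Hfq-FLAG strain (10 libraries) was compared with RNA from the same purification of the WT strain (10 libraries). The WT libraries were taken as the background. Summed depth per library ran from 10249480 to 52855004, and counts outside rRNA genes ran from 33351 to 416753. The libraries together covered 84.0% of the chromosome. Positions are coordinates on the + strand of the MG1655 chromosome.

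The comparison between genotypes asks which RNAs the tagged protein carried through the purification. The largest rise was in oxyS (b4458, 4158278 to 4158394), the sRNA made in oxidative stress, at 393 ± 145 CPM (counts scaled to library size with TMM factors) in Hfq-FLAG and 30.03 ± 19.6 in WT (SD, n = 10 each). This is a 13.2-fold rise (log2 3.72 ± 0.32 SE, edgeR adjusted p = 7.37e-09). Spot 42 (spf, b3864, 4049899 to 4050009), which represses genes for the use of secondary carbon sources, rose 7.41-fold from 138 ± 27.8 to 1030 ± 382 CPM (SD, n = 10 each). The chitoporin repressor chiX (b4585, 507204 to 507287) rose 4.81-fold from 389 ± 157 to 1861 ± 705 CPM, and gcvB (b4443, 2942696 to 2942901), which represses amino acid and peptide transporters, rose 4.21-fold from 257 ± 58.2 to 1079 ± 308 CPM. The rpoS activator dsrA (b1954, 2025223 to 2025313) rose 5.42-fold from 19.3 ± 10.01 to 102 ± 42.4 CPM. For these 5 sRNAs each of the 10 Hfq-FLAG libraries lay above the highest WT library.

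Smaller rises came from micF (b4439), the repressor of the porin OmpF, at log2 1.66 ± 0.29 (SE, 20 libraries), and from glmZ (b4456), the activator of glucosamine-6-phosphate synthase, at 1.38 ± 0.24. The spacer fragment 3'ETS-leuZ (b4759), which is released from a tRNA precursor and pairs with other sRNAs, rose by 1.87 ± 0.34. In these 3 genes 6, 7 and 8 of the 10 Hfq-FLAG libraries, in that order, lay above the highest WT library. The small protein gene spfP (b4837) lies inside spf, so its log2 fold of 2.91 ± 0.20 cannot be separated from that of the sRNA, and chiX shares its right end with ybaP in tables without strand. Counts over the annotated span of ycfJ (b1110, 1167599 to 1168138), which encodes an uncharacterised membrane protein, rose by 2.33 ± 0.27, with 9 of 10 Hfq-FLAG libraries above the highest WT library. This rise lay at the stop codon, and the coding sequence before it had a log2 fold of 0.69 (95% interval -0.06 to 1.43).

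In all, 2823 genes were tested, 12 were higher and 1 was lower, and edgeR gave 228 genes at an unadjusted p under 0.05. The count of lower genes was 25 with DESeq2, 40 at 2 against 2 and 0 at 5 against 5. Leaving out single libraries gave 0 to 15 lower genes, with 15 without WT letter C of either title replicate, 9 without WT E of title replicate 2, 4 without WT E of title replicate 1 or WT D of title replicate 2, and 2 without Hfq-FLAG B of title replicate 1. Outside the naming rule, and so picked after their values were seen, were rybB, waaU and arnB. The envelope stress sRNA rybB (b4417) rose by 1.33 ± 0.25 but missed the threshold at 2 against 2 (edgeR adjusted p = 0.0614). The lipopolysaccharide gene waaU (b3623) rose by 1.46 ± 0.29 and missed it at 5 against 5 (edgeR adjusted p = 0.119). The only called fall was in the lipid A modification gene arnB (b2253), at -1.74 ± 0.39 (edgeR adjusted p = 0.0260), and it was lost at 5 against 5 (edgeR adjusted p = 0.521). Leaving out any of 11 single libraries, namely WT letter A or B of title replicate 2 or each Hfq-FLAG library except letter B of title replicate 1, also ended this call and left 0 lower genes, with log2 folds between -1.86 and -1.36 over all 20 omissions. Within title replicate 1 alone 8 of the 12 were called, without 3'ETS-leuZ, micF, waaU and glmZ, and within title replicate 2 alone 10 were called, without rybB and waaU. Without the WT libraries of letters A and B, 13 genes were higher, 11 of them among the 12, and 0 were lower by edgeR. Scaling by total counts moved the median log2 fold of all genes by -0.13, scaling by rRNA and tRNA genes by -0.15, and the highest depth per gene by -0.12. Under each of the first 2 of these, 9 of the 12 were called, without rybB, 3'ETS-leuZ and waaU.

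RNAs that work with other proteins showed no called change. The RNA polymerase regulator ssrS had a log2 fold of 0.06 ± 0.20 (SE, 20 libraries), the ribosome rescue RNA ssrA 0.11 ± 0.22, the ribonuclease P RNA rnpB 0.12 ± 0.17 and the signal recognition particle RNA ffs 0.07 ± 0.24. The CsrA-binding RNAs csrB and csrC had -0.33 ± 0.22 and -0.28 ± 0.23, and glmY, a decoy for the adaptor of glmZ cleavage, had 0.05 ± 0.19. The highest upper 95% bound among these 7 was 0.56, less than the 2-fold threshold. The fold of glmY turned negative under each of the 3 scalings that shift the median, and those of ssrA and ffs under the highest depth per gene. The mRNA of hfq itself had 0.04 ± 0.38, with a 95% interval from -0.75 to 0.83, and was also negative under those 3 scalings.

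**Figure D1:**
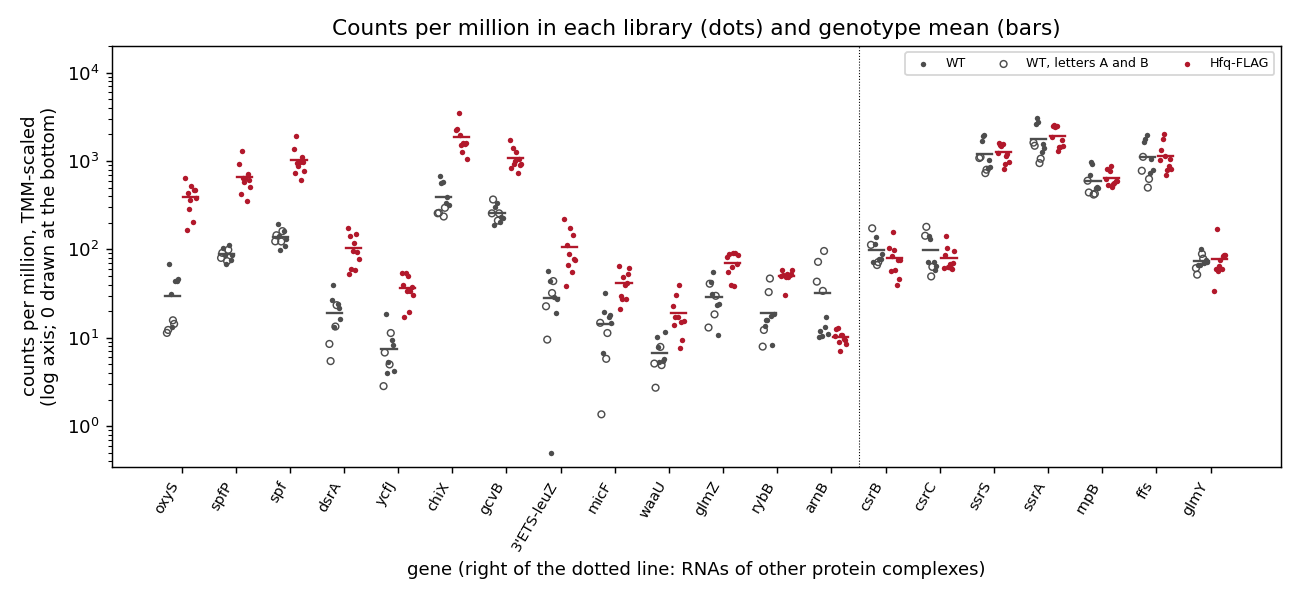
CPM on a log axis for the 13 called genes and 7 RNAs of other protein complexes, with a dot per library, open symbols for WT libraries of letters A and B, and bars at the mean of 10 libraries. For oxyS the Hfq-FLAG libraries lie between 167 and 639 CPM and the WT libraries between 11.4 and 67.7.

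Ribosomal RNA made up most of both purifications, with 84.8 ± 4.06% of the depth in Hfq-FLAG and 84.1 ± 5.22% in WT (SD, n = 10 each). The listed Hfq-binding sRNAs took 0.511 ± 0.160% in Hfq-FLAG and 0.2001 ± 0.116% in WT (permutation p = 0.00025, adjusted p = 0.0015 over 6 classes). Of the depth outside rRNA they took 3.36 ± 0.688% against 1.21 ± 0.385%, and the lowest Hfq-FLAG library, at 2.68%, lay above the highest WT library, at 1.83%. Within each title replicate, and with letters as samples, the difference in this share had an exact permutation p of 0.00794, the smallest that 5 against 5 can give. Coding RNA took 60.02 ± 3.003% of the depth outside rRNA in Hfq-FLAG and 64.4 ± 4.93% in WT, a difference that missed the threshold after adjustment over the 20 libraries (permutation p = 0.0296, adjusted p = 0.0740) and within title replicate 1 (exact adjusted p = 0.526). It passed within title replicate 2 (exact adjusted p = 0.0199) and with letters as samples (exact adjusted p = 0.0397). The coding class here also held pseudogenes and ssrA. For tRNA the share outside rRNA was 16.2 ± 1.64% in Hfq-FLAG and 13.8 ± 3.04% in WT (permutation p = 0.0453, adjusted p = 0.0756). The classes share the same total, so a fall in coding RNA cannot be assigned to the rise of the sRNAs alone.

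T-to-C changes, the mark of the cross-link, were examined by RNA class after the data were seen. In the listed sRNAs 5.77 ± 0.316% of read bases at transcript T were read as C in Hfq-FLAG and 1.18 ± 0.408% in WT (SD, n = 10 each). The lowest Hfq-FLAG library had 5.18% and the highest WT library 1.80%. The permutation p was 1e-05 and the adjusted p over 12 substitutions 0.00012, the smallest that these permutations can give. The share was 5.62% against 0.916% within title replicate 1 and 5.91% against 1.45% within title replicate 2. In rRNA it was 0.656 ± 0.207% against 0.661 ± 0.285%, in coding RNA 0.823 ± 0.228% against 0.772 ± 0.325%, and in tRNA 0.866 ± 0.103% against 0.820 ± 0.113%. Over all RNA, most of it ribosomal, the difference was smaller than the spread between libraries (0.715 ± 0.223% against 0.673 ± 0.284%, permutation p = 0.719).

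Other ncRNAs had 1.99 ± 0.547% T-to-C in Hfq-FLAG and 0.518 ± 0.292% in WT (permutation adjusted p = 0.00012, again the smallest possible). Only genes with a resolved strand entered these percentages, so ffs, ssrS and rnpB were left out. Other ncRNAs also included 3'ETS-leuZ and aceK-int, which are not on the sRNA list and had a higher share gene by gene. All RNA outside rRNA had 1.31 ± 0.248% against 0.794 ± 0.259% (permutation adjusted p = 0.00564). With letters as samples, both of these classes had an exact permutation p of 0.00794, the smallest that 5 against 5 can give. Adjusted over 12 substitutions this is 0.0953, so a single changed substitution could not pass 0.05 there. Among the other 11 substitutions in the listed sRNAs, T-to-A was higher in Hfq-FLAG (0.341 ± 0.0802% against 0.206 ± 0.112%, permutation adjusted p = 0.0172), and 4 were lower, the largest difference being in A-to-G (0.1695 ± 0.0455% against 0.355 ± 0.0861%).

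**Figure D2:**
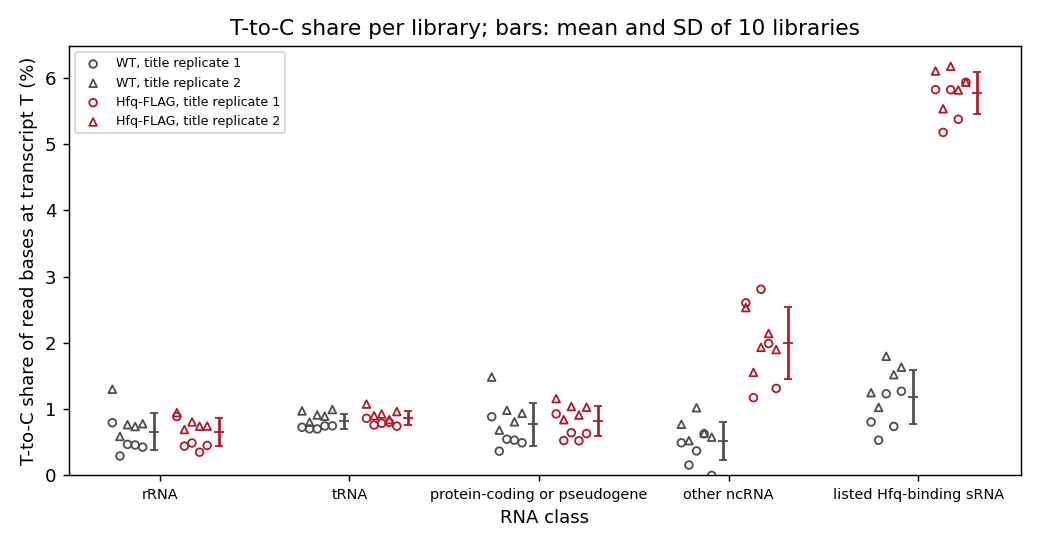
Percentage of read bases at transcript T that were read as C, by RNA class, with a symbol per library, circles for title replicate 1, triangles for title replicate 2, and bars for the mean and SD of 10 libraries. In the listed sRNAs the Hfq-FLAG libraries start at 5.18% and the WT libraries end at 1.80%, while the genotypes overlap in rRNA, tRNA and coding RNA.

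Gene by gene, with letters as samples, 24 genes had a higher T-to-C share in Hfq-FLAG, on their own strand except for pspH, whose strand was not resolved and whose change was on the + strand. They included 14 of the 21 listed sRNAs with enough read bases and 10 of 530 other genes (Fisher's exact test over genes, odds ratio 99.4, adjusted p = 1.1e-15 over 13 lists). Of the 7 stable ncRNAs of other protein complexes, 0 had a higher share. As a control, limma called 0 of 777 genes for C-to-T and 0 of 777 for G-to-A, with 58 and 62 at an unadjusted p under 0.05. For T-to-C on the + strand it called 13 of 528 genes higher and 2 lower, and for A-to-G, the same change on the other strand, 11 of 527 higher and 1 lower. The lower ones were dsrA, 3'ETS-leuZ and spf, each for the change that belongs to the strand opposite the RNA. Within title replicate 1 alone limma called 4 of 213 genes higher for T-to-C and 1 of 213 for A-to-G, and within title replicate 2 alone 12 of 401 and 10 of 402.

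Of these 14 sRNAs 8 also had a rise in counts called by edgeR over 20 libraries. Their T-to-C shares in Hfq-FLAG and WT were 7.42 and 2.90% in spf, 6.44 and 2.73% in oxyS, and 5.56 and 1.79% in chiX. They were 5.26 and 1.54% in dsrA, 5.55 and 1.16% in gcvB, 6.06 and 1.25% in glmZ, 4.38 and 0.706% in rybB, and 5.25 and 0.487% in micF. Why the WT share differed between these RNAs was not tested. The other 6 sRNAs had no called rise in counts. In sroC, which is released from the gltI mRNA and pairs with gcvB, the share was 9.40 ± 1.82% in Hfq-FLAG and 1.12 ± 1.16% in WT (SD, n = 5 letters each, limma adjusted p = 0.000223), and the log2 fold of counts was -0.98 (95% interval -2.13 to 0.17). In arcZ, an activator of rpoS that overlaps arcB, the share was 5.17 ± 0.819% against 0.607 ± 0.414%, and the log2 fold was -0.10 (-0.72 to 0.52). In ryhB, the iron limitation sRNA, it was 5.01 ± 1.36% against 0.490 ± 0.471%, and the log2 fold was -0.26 (-1.13 to 0.62). The curli and motility regulators mcaS and omrA had 6.94 ± 1.90% against 1.39 ± 0.557% and 4.96 ± 2.33% against 1.71 ± 1.14%, with log2 folds of 0.81 (0.24 to 1.38) and -0.13 (-0.99 to 0.74). In counts mcaS was called higher with limma-voom, and with edgeR when WT letter B of title replicate 1 was left out. The rpoS activator rprA had 2.15 ± 0.558% against 0.586 ± 0.543%, and a log2 fold of -0.01 (-0.47 to 0.44). The T-to-C calls of omrA and rprA lay near the threshold. That of omrA (limma adjusted p = 0.0202) was lost in 6 of 10 fits that left out a letter, namely WT A, B or C or Hfq-FLAG A, D or E, with adjusted p up to 0.151, while its log2 odds difference stayed between 1.72 and 2.36 over the 10 fits (2.08 with all letters). That of rprA (limma adjusted p = 0.0380) was lost in 9 of 10, all but the fit without WT C, with adjusted p up to 0.217 and log2 odds differences from 1.28 to 1.93 (1.59 with all letters). Title replicate 2 alone called both, at 1.95 for omrA and 1.79 for rprA (limma adjusted p = 0.0111 and 0.00906). Without WT letters A and B, 5 letters against 3, the limma adjusted p was 0.607 for omrA, whose log2 odds difference went from 2.08 to 1.02, and 0.469 for rprA, at 1.43, and the other 12 of the 14 sRNAs were called. These 12 were also called in each of the 10 fits.

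These 6 folds moved when the WT libraries of letters A and B were left out. The log2 folds then were 1.54 for mcaS and 1.62 for omrA, both called (edgeR adjusted p = 0.0014 and 0.00519), and 0.87 for arcZ, 1.02 for sroC, 0.94 for ryhB and 0.50 for rprA, none called. With letters summed, 5 against 3, arcZ at 1.06 and sroC at 1.23 were called as well (edgeR adjusted p = 0.0201 and 0.0208), and ryhB at 1.12 and rprA at 0.58 were not (0.209 and 0.588).

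The other genes with a higher T-to-C share, all singled out after their values were seen, were spfP, 3'ETS-leuZ, pspH, ispZ, ompF, wzzB, aceK with the RNA aceK-int inside it, yhcN and aspC. The porin mRNA ompF, a target of micF, had 3.30 ± 0.405% against 1.33 ± 0.320% (SD, n = 5 letters each, limma adjusted p = 0.00288), and a log2 fold of counts of -0.41 (95% interval -0.83 to 0.02). The RNA pspH, whose strand was not resolved, had 6.07 ± 1.00% against 0.502 ± 0.460%. In wzzB, which sets the length of O-antigen chains, the share was 3.65 ± 1.85% against 0.435 ± 0.401%. Leaving out a letter ended the calls of aceK and aceK-int (WT A or B or Hfq-FLAG D, limma adjusted p up to 0.0805), yhcN (WT A or Hfq-FLAG A or D, up to 0.105) and aspC (WT A or B or Hfq-FLAG C or D, up to 0.104). The log2 odds differences over the 10 fits stayed between 1.86 and 2.71 for aceK (2.35 with all letters), 1.88 and 2.74 for aceK-int (2.37), 2.67 and 3.39 for yhcN (2.90), and 1.87 and 2.25 for aspC (2.07). At 5 letters against 3 these 4, wzzB and 3'ETS-leuZ were not called. The difference there was 2.50 for wzzB (2.51 with all letters, limma adjusted p = 0.0501 at 5 against 3), 2.11 for aspC and 4.19 for yhcN, and it was smaller for aceK with aceK-int (1.31 for aceK) and for 3'ETS-leuZ (1.32, from 1.80). The lists of sRNA target mRNAs and outer membrane proteins had 1 member each with a higher share, which was ompF in both. Only 22 of the sRNA target mRNAs and 13 of the outer membrane genes had enough read bases for this test. It summed changes over the annotated gene, so untranslated ends of mRNAs were left out.

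**Figure D3:**
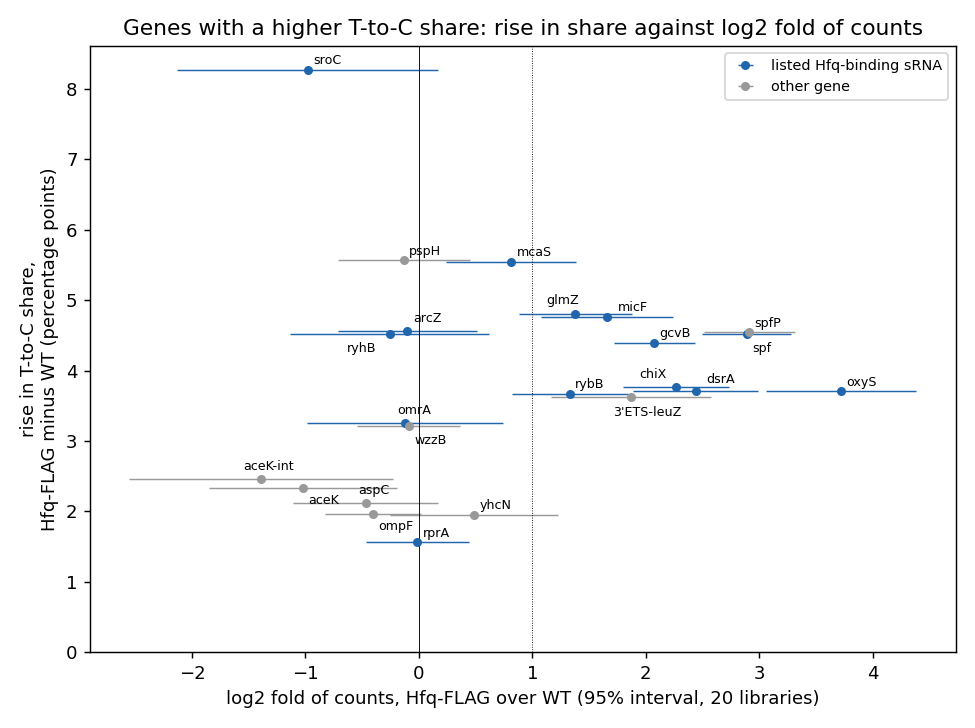
Rise in the T-to-C share in percentage points (Hfq-FLAG minus WT, 5 letters each) against the log2 fold of counts with its 95% interval over 20 libraries, for genes with a higher share, blue for listed sRNAs and grey for other genes. The RNA sroC stands at a log2 fold of -0.98 and oxyS at 3.72, and the dotted line marks a 2-fold rise.

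The most changed position of a gene was also examined. In gcvB the site T2942866C was read as C in 21.7% of 2095 read bases in Hfq-FLAG and 2.67% of 450 in WT, pooled over libraries. In micF the site T2313134C had 32.2% of 351 against 2.41% of 83, and in arcZ T3350642C had 26.4% of 250 against 1.28% of 312. On the other strand, sroC A686838G had 52.6% of 430 against 1.75% of 914 and mcaS A1405698G had 35.4% of 378 against 2.67% of 150. These sites were chosen as the most changed of each gene, so their percentages lie above the gene's mean.

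Windows of 50 nt were compared to find bound parts that gene annotation leaves out. Of 2263 windows 15 were higher, among them 3 each in gcvB and spf and 2 each in oxyS and chiX, and edgeR called 0 lower (91 windows had an unadjusted p under 0.05, and 19 were at least 2-fold lower at that level). At 2 against 2 edgeR called 43 higher and 152 lower. Genes for ncRNA held 11 of the 15 and 74 of 2248 other windows (Fisher's exact test, odds ratio 80.03, adjusted p = 9.26e-13). Windows inside coding sequences made up 0 of the 15 and 784 of the others (adjusted p = 0.00723), and rRNA windows 0 of the 15 and 642 of the others (adjusted p = 0.0206, or 0.0951 with a 4-fold threshold). A run of at least 5 T on either strand lay in 8 of the 15 and 216 of 2230 others (Fisher's exact test, odds ratio 10.6, adjusted p = 6.03e-05). A repeat of at least 3 A-R-N triplets on either strand, where R is A or G, lay in 9 of the 15 and 355 of 2230 (odds ratio 7.91, adjusted p = 0.000142). A long T run also matches this repeat when read from the opposite strand, so the motifs overlap and are not separate results. Neighbouring windows of the same RNA are not independent, so these p-values are too small.

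A narrow peak sat on the stop codon of ycfJ. From 1168101 to 1168200 the Hfq-FLAG libraries held 902 counts and the WT libraries 84, and the window from 1168101 to 1168150 had a log2 fold of 4.08 (95% interval 3.19 to 4.98). The ycfJ coding sequence before the peak held 116 and 96 counts and had a log2 fold of 0.69 (-0.06 to 1.43). In the peak 8.20 ± 0.893% of T were read as C in Hfq-FLAG (SD, n = 5 letters), against 12 of 638 read bases in WT. A peak between symR and hsdS, from 4579951 to 4580050, held 611 counts in the 10 Hfq-FLAG libraries and 8 in WT, where 4 of 10 libraries had a count. It was tested only with letters as samples (edgeR adjusted p = 0.0188), and 7.77 ± 1.03% of its T were read as C in Hfq-FLAG (SD, n = 5 letters). In WT 2 of 42 read bases were read as C there, too few to compare, and both lay among the 22 of letter C (9.09%, against 7.28% in Hfq-FLAG letter C). Since most positions had an even depth, these 2 may not come from separate fragments. Just upstream of the tRNA gene proM, the window from 3982701 to 3982750 held 1051 against 482 counts, a log2 fold of 1.36 ± 0.24 (edgeR adjusted p = 0.00124), with 9.79 ± 2.62% T-to-C before the tRNA (SD, n = 5 letters) against 24 of 1399 in WT. These 3 peaks were singled out after their values were seen. Their T-to-C shares took every position with T as the leading base, without the consensus limits on depth and base share. They are therefore not directly comparable with the shares of genes and RNA classes.

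Substitutions per window added places that the gene test did not call. Of 2476 windows limma called 15 higher and 1 lower for T-to-C, and of 2542 it called 3 higher and 0 lower for A-to-G. For C-to-T and G-to-A it called 0 of 3164 and 0 of 3188, with 255 and 285 at an unadjusted p under 0.05. In micA, the repressor of the porin OmpA, the share was 6.89 ± 2.51% against 0.398 ± 0.395% (SD, n = 5 letters each, limma adjusted p = 0.000871). A window between yodB and serU, from 2043101 to 2043150, had 6.04 ± 2.66% against 0.102 ± 0.141% (limma adjusted p = 0.0012). A window overlapping hupB, from 461451 to 461500, had 2.96 ± 1.87% against 0.125 ± 0.279% (limma adjusted p = 0.0310). This gene encodes a subunit of the nucleoid protein HU. A window overlapping the tRNA gene proM, from 3982801 to 3982850, had 7.66 ± 1.74% against 1.38 ± 0.408% (limma adjusted p = 0.000748). The peak upstream of proM is therefore not the only part of this locus with a higher share. A window in rpoB, from 4181551 to 4181600, had 1.85 ± 0.608% against 0% (limma adjusted p = 0.00364).

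**Figure D4:**
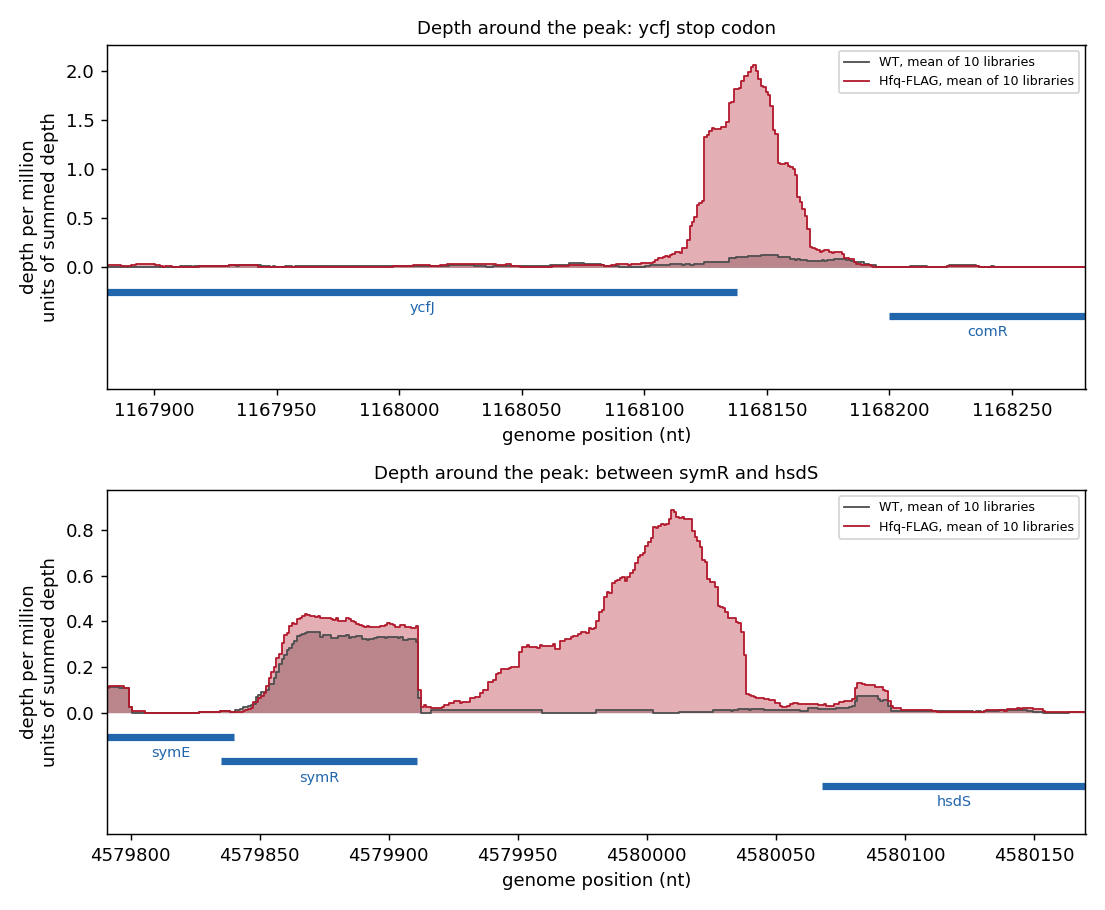
Mean depth per 1000000 units of the summed depth of each library, without TMM factors, over 10 libraries of each genotype along the chromosome, with annotated genes as bars below, around the stop codon of ycfJ and between symR and hsdS. At 1168145 the mean is 2.06 in Hfq-FLAG and 0.115 in WT, and at 4580010 it is 0.887 and 0.

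Of the 13 gene lists, 5 were called by camera with its preset correlation. The Hfq-binding sRNAs were called up (adjusted p = 3.2e-10), and also with fry (0.00219) but not with an estimated correlation (0.0600). Of 31 tested 8 were higher, 0 lower and 23 not called, and 8 were higher and 3 lower when adjusted over the list alone. Their median log2 fold was -0.01 and their mean 0.30, so the median differs in sign from the mean and the test. General stress response genes were called down (14 tested, 1 with a positive fold, median -0.68, adjusted p = 1.87e-05), as were sugar transport (32 tested, 7 positive, median -0.20, adjusted p = 0.00592) and amino acid and peptide transport (43 tested, 12 positive, median -0.17, adjusted p = 0.010). Each of these 3 had an adjusted p of 0.181 with the estimated correlation. Flagella and motility genes were called up (31 tested, 22 positive, median 0.12, adjusted p = 0.0398, or 0.532 with the estimated correlation). In these 4 lists edgeR called 0 genes one by one (8 general stress, 11 sugar transport, 8 amino acid transport and 2 flagella genes had an unadjusted p under 0.05), and adjusted over the list alone 2 general stress and 3 sugar transport genes were lower. Without the WT libraries of letters A and B the sRNA list alone remained called, and the general stress and flagella lists changed direction (adjusted p = 0.985 for both).

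The other 8 lists were not called, and none of their genes was called by edgeR, over all genes or adjusted over the list alone. At most 11 genes of any of these lists, in the sRNA target mRNAs, had an unadjusted p under 0.05. The adjusted camera p was 0.711 for iron uptake and iron-containing proteins (38 tested), 0.886 for outer membrane proteins (33) and for type I toxin-antitoxin and antisense RNAs (12), and 0.290 for ribosomal proteins (54) and for sRNA target mRNAs (71). It was 0.977 for RNA degradation and RNA chaperones (27) and for stable ncRNAs of other protein complexes (7), and 0.201 for the tricarboxylic acid cycle (19). Median and mean differed in sign for outer membrane proteins (0.03 and -0.03), RNA degradation (-0.02 and 0.02) and stable ncRNAs (0.06 and -0.03). For RNA degradation the test followed the mean, and for outer membrane proteins the median. For stable ncRNAs it followed the mean.

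Within the WT genotype, the 4 libraries of letters A and B had 33.9 to 95.9 CPM of arnB, the other 6 WT libraries 10.2 to 17.4, and the Hfq-FLAG libraries 7.02 to 12.8. The libraries A of title replicates 1 and 2 had 407 and 130 CPM of sroC and those of B 598 and 179, while the other 6 WT libraries had 19.1 to 90.8. The acid stress sRNA gadY (101, 92.3, 155 and 167 CPM) and malH (122, 66.3, 252 and 133 CPM) were high in the same 4 libraries, in that order. Their T-to-C share in the listed sRNAs was 0.806, 1.25, 0.532 and 1.03%, within the range of the other WT libraries or below it.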

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

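The test of a swap in this part was chosen after the result was seen. Of 116 groups of 10 libraries examined, 13 held a library far from the other 9, where chance gives about 1 in 20 groups. The libraries behind them were few, with WT letter B giving 5 of the 13 and Hfq-FLAG letter C of title replicate 1 giving 3.

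In the WT library of letter B and title replicate 1, malH stood at 252 CPM (next WT library 133), raiZ at 215 (next 65.2), mcaS at 77.7 (next 42.3) and ryjB at 39.5 (next 17.6). In WT letter B of title replicate 2, cpxQ stood at 57.0 CPM (next 31.6). In Hfq-FLAG letter C of title replicate 1, which had the fewest counts outside rRNA (33351), chiX stood at 3528 CPM (next Hfq-FLAG library 2306), csrC at 141 (next 103) and glmY at 170 (next 86.6). Hfq-FLAG letter B of title replicate 1 had 65.0 CPM of fliX (next 28.4). Hfq-FLAG letter D of title replicate 1 had the lowest rybB, at 30.2 CPM (next 48.4), and WT letter D of title replicate 1 had the highest hfq, at 109 CPM (next 67.9). In WT letter A of title replicate 2 the T-to-C share stood at 1.3% over all RNA (next 0.799%) and at 1.3% in rRNA (next 0.795%).

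The WT libraries of letters A and B differed from the other WT libraries in arnB and in several sRNAs. A swap with Hfq-FLAG libraries would give them a high T-to-C share in listed sRNAs, and the highest of the 4 had 1.25% while the lowest Hfq-FLAG library had 5.18%, which argues against it. A difference in how the cultures of letters A and B were grown or processed stays open and was not tested, since the labels do not say what the letters or the replicate numbers stand for. The labels name no growth difference, so no biological explanation was tested.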

How the results depend on the processing

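Fits without WT letters A and B, 5 letters against 3, 60 units per count, list tests at 5 against 5 and all substitution alternatives were chosen after the result was seen. Over 44 named genes and 1662 alternatives, 1617 kept their side of the threshold without a called reversal, 32 fell short of it, 9 newly passed it and 4 reversed. Among the 1617 were 126 uncalled values that changed sign. The shortfalls were in arnB, waaU, 3'ETS-leuZ, rybB, glmZ and micF. Genes that the filter of a setting left out were not counted among these. With 10 counts in every library of a group, and with 60 units per count, 9 of the 12 higher genes were called, without ycfJ, micF and waaU. Each time a library was left out, the 12 higher genes stayed among 12 to 14 called. The replicate block gave 12 higher genes, the same 12, and 1 lower. Libraries of the same letter in both genotypes were no closer to each other than other libraries (highest r 0.16), so the comparison was left unpaired. Across the genotypes, libraries of the same title replicate number were closer (mean r 0.13) than those of different numbers (mean r -0.11). With the letter as a block across the genotypes 12 genes were higher, the same 12. Within WT the libraries of a letter correlated across title replicates (r 0.21 to 0.56, above every other letter in 4 of 5), and within Hfq-FLAG less (r -0.02 to 0.15), so the 20 libraries are not fully independent. At 5 against 5, with letters as samples, 12 genes were higher and 11 of them were among the 12 of the 20 libraries. The title replicate 1 fit tested 1591 genes and called 8 higher. Where the construction of an alternative does not show it, the cause was not tested.

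The count of lower genes varied widely. It was 2 with total counts, 3 with rRNA and tRNA factors, 25 with DESeq2, 2 with no filter, 0 with 10 counts in every library of a group, 3 with the highest depth, 3 with the letter block, 2 with the replicate block and letter block together, 0 at 5 against 5, 40 at 2 against 2, 0 in title replicate 1, 0 without WT A and B, 0 at 5 letters against 3 and 0 with 60 units. Leaving out single libraries gave 0 to 15. It was 15 without WT letter C of either title replicate, 9 without WT E of title replicate 2, 4 without WT E of title replicate 1 or WT D of title replicate 2, 2 without Hfq-FLAG B of title replicate 1, and 0 without WT A or B of title replicate 2 or without any of the other 9 Hfq-FLAG libraries. The fold of arnB ranged from -1.86 to -1.36 over these.

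Higher windows numbered 43 at 2 against 2 and 24 without WT A and B, and lower windows 1 at 5 against 5, 152 at 2 against 2 and 1 with shifted windows. With a 4-fold threshold rRNA windows stayed at 0% of the higher windows, but the adjusted p rose to 0.0951 as fewer windows were called. The coding share outside rRNA passed the threshold in title replicate 2 (-4.83 percentage points) and with 5 letters (-4.41).

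With an estimated correlation 0 lists were called, at adjusted p 0.0600 for the sRNAs, 0.532 for flagella and 0.181 for general stress, sugar transport and amino acid transport. With fry 1 was called, with 0.444 for flagella and 0.1001 for the other 3. Without WT A and B 1 was called, with 0.638 for amino acid transport, 0.664 for sugar transport, and reversed signs for general stress and flagella (0.985 each). Ribosomal proteins passed at 5 against 5 (0.0405).

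The T-to-C difference, uncalled over all RNA, was called outside rRNA (0.516 points), in listed sRNAs (4.59) and in other ncRNAs (1.48). Genes with a higher T-to-C share numbered 4 in title replicate 1, and with a lower share 0 there, 1 in title replicate 2, 1 at 5 letters against 3 and 1 to 2 without single letters. Genes with a higher A-to-G share numbered 1 in title replicate 1 and 7 at 5 letters against 3. Those with a lower share numbered 0, 2 and 0 in title replicate 1, title replicate 2 and 5 letters against 3, and 0 to 3 without single letters (3 without WT A, 2 without WT E). Reversed to called rises were omrA, at 1.62 without WT A and B and 1.70 at 5 letters against 3, and arcZ (1.06) and sroC (1.23) at 5 letters against 3.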

Other observations

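The tests chosen after the result was seen were those on the general error rate, on the WT libraries of letters A and B, on the whole ycfJ transcript, on cross-linked RNA in the peaks and on splits that keep letters together, while the other splits of the samples and the test for reads mapped to the wrong place were set before. The sRNAs with the largest rise in counts, oxyS, spf, chiX, gcvB and dsrA, also carried more T-to-C changes in the Hfq-FLAG strain, while RNAs of other protein complexes had no called rise in either. By both measures sRNAs were the class with the clearest difference between the genotypes in mid log phase. Coding RNA as a class showed little of this. Of the 75 listed sRNA target mRNAs 22 had enough read bases for the T-to-C test, and among these only ompF had a higher share. That test covered the annotated gene as a whole, so untranslated ends were left out and a change at a single site was averaged over the gene. The other listed targets could not be tested for it.

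Other splits of the 20 libraries into 10 and 10 were compared with the real one, 100 in all with the real one included. For genes, 2 of 100 splits called at least the real 13, and the highest other called 27. Chance is therefore unlikely as the source of the count but is not excluded. Of the 99 other splits 12 had all 4 WT libraries of letters A and B on the same side, of which 8 called 0 genes and 4 called 1, 2, 3 and 27, and 0 splits with these libraries apart called a gene. This points to a structure of the samples that alone does not give calls in most splits. For windows, 1 of 100 splits reached the real 15 (highest other 8). For substitutions, 1 of 100 reached the real 27 per gene (highest other 4) and 1 of 100 the real 19 per window (highest other 2). Chance is unlikely as the source of these counts. For lists, 33 of 100 splits called at least the real 5 (highest other 9), so chance cannot be excluded for the number of called lists.

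These splits treat libraries as exchangeable, although WT libraries of the same letter resembled each other. With both libraries of a letter kept together in each genotype, 3 of 100 splits called at least the real 13 genes (highest other 23). For windows 1 of 100 reached the real 15 (highest other 3). Chance is again unlikely for both counts, but it is not excluded for genes. For lists 43 of 100 splits called at least the real 5 (highest other 11), so chance cannot be excluded there. Of the 99 other splits by letter 46 had WT letters A and B on the same side, and 10 of these called genes, the split with 23 among them, against 1 with A and B apart.

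The sRNAs arcZ, sroC, ryhB, mcaS, omrA and rprA had more T-to-C with 5 letters in each genotype but no rise in counts called by edgeR over 20 libraries. The T-to-C calls of omrA and rprA were lost in 6 and 9 of 10 fits without a single letter and at 5 letters against 3 (limma adjusted p 0.607 and 0.469). For omrA these letters were WT A, B or C or Hfq-FLAG A, D or E, and for rprA each letter but WT C. Over the 10 fits the log2 odds differences stayed at 1.72 to 2.36 for omrA and 1.28 to 1.93 for rprA, so these calls lay near the threshold while the differences remained. At 5 letters against 3 they were 1.02 and 1.43. A higher general error rate in the Hfq-FLAG libraries would raise C-to-T and G-to-A too, but their median log2 odds difference over the 6 RNAs was 0.21 (SD 0.38) while the lowest T-to-C difference was 1.59, which argues against it, although 3 of 12 control tests had an unadjusted limma p under 0.05. Without WT letters A and B the log2 fold of rprA was 0.50 with an upper bound of 0.94, just below a 2-fold rise. That fit took libraries of the same letter as independent, so the bound may be too low. With letters summed, 5 against 3, the log2 fold was 0.58. These values argue only weakly against a 2-fold rise of rprA hidden by high counts in those libraries, and do not exclude it. For mcaS, omrA, arcZ, sroC and ryhB such a hidden rise was left open, since leaving out WT libraries with high counts of an RNA raises its fold in any case. Whether these RNAs were truly more abundant in the cultures of letters A and B was not tested.

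The peaks on the ycfJ stop codon, between symR and hsdS, and upstream of proM may be RNA fragments bound by Hfq. The longest run of identical bases that a peak shared with a called RNA was 11 nt, shorter than the median isolated run of 13 nt. Matches with mismatches and RNAs that were not called were not compared. Short reads mapped to the wrong place are therefore not excluded. A rise of the whole ycfJ transcript is argued against by the coding sequence before the peak, at 0.69 against 4.08 in the peak. In 15 of 15 letter sums over the 3 peaks the T-to-C share in Hfq-FLAG lay above that of coding RNA. The 2 measures are unlike. The peaks took every position with T as the leading base, while coding RNA was limited to positions that met the consensus limits on depth and base share. Each WT letter sum upstream of proM, and some at the ycfJ stop codon, also lay above WT coding RNA. This count alone therefore does not point to the tagged strain. The mean Hfq-FLAG share was 8.20% at ycfJ and 9.79% upstream of proM, against a pooled 1.88% and 1.72% in WT. A window overlapping proM itself, from 3982801 to 3982850, also had a higher share (7.66% against 1.38%). Between symR and hsdS the WT libraries held 42 read bases, too few to tell whether the share differed between the genotypes. What RNAs these are, and their strand, cannot be read from these tables beyond the T-to-C changes on the + strand.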
